A study of Mus musculus with 4 samples.

How the data were processed

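RNA was measured by bulk sequencing of CD140b-positive mouse lung cells in 4 libraries, 2 from littermate controls and 2 from Foxf2 KO mice, grouped by their sample titles. Per the labels' protocols, lungs were digested with dispase, collagenase and DNase, red cells were lysed, cells were captured with a biotin-conjugated CD140b antibody and magnetic beads, and libraries were made with a NEBNext Ultra RNA kit. Per the labels, KO replicate 2 is batch 2 and the other 3 libraries are batch 1.

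Per the submitters' processing notes, reads were aligned with HISAT2 to mm10. The authors deposited raw counts per gene for each library, made with featureCounts 2.0.1 per the file headers. Per the file headers these counts are of read pairs over exons summed by gene identifier of the mm10 RefSeq gene annotation, with no option for strand, multiply mapped reads or overlapping genes. Reads that map equally well to near-identical genes, or that overlap 2 genes on opposite strands, therefore leave the counts or cannot be told apart. Each deposited count table has 25239 genes and no rows for unassigned reads. The versions of HISAT2 and of the authors' DESeq2 are not given in the sources used here.

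The authors also deposited a table of their own comparison, whose column names are those of DESeq2 results, which the submitters' processing notes name. It gives, per the file headers, a mean normalized count per gene (a signal, in the authors' scaling), log2 fold changes with their standard errors, a Wald statistic (a score), and a p-value with its adjusted p-value. The authors' design formula, size factors and filter are not given in the sources used here. The authors' mean normalized counts were 1.61 times those of the deposited counts at the median gene, and the reason was not tested. Its values are printed only as the authors' own.

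The depth ranged from 22764638 to 27984511 counts, with 17374 to 17543 genes detected. A floor of 3 counts corresponds to 0.107 to 0.132 CPM per library and covers counting error only. No pair of libraries differed by less than sampling noise: the chi-square statistic per gene was 46.6 between the controls and 76.3 or more for other pairs. The list of mitochondrially encoded genes had 0 measured genes and was left out, and of the sex-linked list only Xist passed the filter.

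Counts were analysed in R 4.3.3 with edgeR 4.0.16: genes were kept by filterByExpr with the group, which kept 99.79% to 99.95% of counts, libraries were scaled by TMM, and KO was compared with control by glmQLFit and glmQLFTest without covariates, with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values use the TMM library sizes. Log2 differences from the control mean are of log2(CPM + 0.5), which understates changes of low genes. The fit has 2 residual degrees of freedom, and 1 with the batch term.

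Gene lists were fixed before the data were examined: 32 lists of cell types, pathways and technical signs, of which 30 had at least 3 measured genes. They were tested with camera in limma 3.58.1 (preset correlation 0.01), beside an estimated correlation and fry, with adjustment over lists. Camera compares a list with all other genes, and fry tests whether its genes move one way on balance. Members were also tested with adjustment over the list alone.

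Named genes followed a rule set before the data were examined. It takes the FoxF list first, then up to 12 genes per direction that pass the threshold, lie beyond both controls and average at least 5 CPM. Symbols of the Gm or Rik kind and pseudogenes were left out. Where fewer than 5 pass, the 5 with the smallest p are taken and said not to pass. It then takes up to 4 members of each passing list and 2 of other lists by smallest p. Genes outside the rule, chosen after their values were seen, are Pdgfrb (the sorted receptor), Col3a1, Lyz2, Dntt, Rag1, Siglecf, Ccr3, Adgre1, Retnlg, Krt18, Sema3c, Hmgn2, Art4, 2610035D17Rik, the first genes of the authors' table and those named in the closing section.

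Alternatives set before the data were examined were DESeq2 size factors, upper-quartile scaling, no filter, a filter of 5 CPM in 2 libraries, limma-voom, DESeq2 1.42.0, a replicate block, a batch term, fewer gene models, other thresholds and leaving out each library. Scaling to the fixed stromal genes, DESeq2 with the batch term, and lists without KO replicate 1 with an estimated correlation were added after the data were seen. The chance agreement of the KO libraries through their shared controls was simulated with dispersions of the controls.

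The scripts were tested on simulated counts with 200 changed genes, 50 of each size, at the means of these libraries. Each gene was drawn at the dispersion typical of its expression level, with no further scatter between genes and no outlying library. The recovered shares can therefore overstate what the tests find in these data. At the spread of all 4 libraries the edgeR test recovered 0%, 16%, 82% and 98% of genes changed by 1, 2, 3 and 4 on the log2 scale, with 1 false call, and DESeq2 made 31 false calls. At the spread of the controls edgeR recovered 62%, 100%, 100% and 100%, with 10 false calls. A list shifted by 2 on the log2 scale was found with the preset correlation at both spreads and missed with an estimated one at both.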

Results

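FOXF2 is a forkhead transcription factor of mesenchymal cells, and the title of the series places it in lung pericytes, the mural cells that wrap capillaries, and in their signalling to the endothelium. The labels of these libraries give no oxygen exposure. CD140b, also called PDGFRβ, is the receptor for platelet-derived growth factor B on pericytes and other mesenchymal cells. Cells carrying it were pulled with magnetic beads from digested lungs of mice at postnatal day 7, and their RNA was sequenced in bulk. The 2 Foxf2 KO libraries came from mice with floxed Foxf2 and a Pdgfrb-driven CreER, a Cre recombinase that tamoxifen activates. The other 2 libraries came from littermate controls. Control replicates 1 and 2 held 22764638 and 24792144 counts, and KO replicates 1 and 2 held 25691460 and 27984511. KO replicate 2 is batch 2 in the labels and the other 3 libraries are batch 1. The labels do not say how many mice went into each library, so p-values measure only the spread between these libraries, which may be technical. An exact two-sided permutation test of 2 against 2 cannot give a p below 0.333.

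All 4 libraries carried both mesenchymal and leukocyte transcripts, and KO replicate 1 stood apart from the other 3. The collagen gene Col3a1 reached 28130 and 16750 CPM (counts scaled to library size) in control replicates 1 and 2, and 6624 and 20660 CPM in KO replicates 1 and 2. Lyz2, the lysozyme gene of macrophages and neutrophils, reached 16000 and 20310 CPM in the controls and 3670 and 13240 CPM in the KO libraries. Dntt and Rag1, genes of receptor rearrangement in developing lymphocytes, were abundant in KO replicate 1 alone. Dntt, the polymerase that adds bases at V(D)J junctions, reached 637.7 CPM there, against 1.73 and 0.758 CPM in the controls and 0.625 CPM in KO replicate 2. Rag1, which cuts DNA in V(D)J recombination, reached 359.2 CPM there, against 1.73, 0.877 and 0.221 CPM. Across genes, the log2 CPM values of the controls correlated at r = 0.978, and those of KO replicate 2 with the controls at 0.971 and 0.975. KO replicate 1 correlated with the other 3 libraries at 0.846 to 0.853. These correlations are across genes, which are not independent replicates. The 111 measured stromal genes, taken from the pericyte, smooth muscle, fibroblast and matrix lists, had a median log2 difference from the control mean of −1.73 in KO replicate 1, which is 30.1% of the control level. Control replicate 2 had 2059 counts of the Y-linked gene Ddx3y and 2 counts of Xist, the X-inactivation transcript. The other libraries had 1 to 6 counts of Ddx3y and 844 to 2385 counts of Xist. The controls thus differed from each other in sex-linked transcripts, and only control replicate 1 was like the KO libraries in them. No fit included a term for sex.

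The first comparison checked the deleted gene. Foxf2 lay lower in both KO libraries than in both controls. It had 27.1 and 56.2 CPM in control replicates 1 and 2, from 609 and 1408 counts. It had 1.56 and 14.5 CPM in KO replicates 1 and 2, from 41 and 395 counts. The means were 41.6 ± 20.6 CPM in controls (SD, n = 2) and 8.04 ± 9.17 CPM in KO (SD, n = 2). The log2 fold change was −2.37 (SE 1.11), and it did not pass edgeR's quasi-likelihood test (adjusted p = 0.755). Within batch 1, where KO replicate 1 stands against both controls, it was −4.74 (adjusted p = 0.00077), and batch 2 holds no control. Without KO replicate 1 it was −1.52 (adjusted p = 0.323), and over all alternatives the adjusted p ranged from 2.54e-20 to 1. As a share of Pdgfrb, Foxf2 was 1.39% and 4.23% in the controls, and 0.401% and 0.478% in KO replicates 1 and 2. Foxf2 lies on chromosome 13 at 31625816 to 31631406 on the plus strand of mm10, with 2 exon intervals in the authors' annotation. Which exon is floxed is not given in the sources used here, and counts over the whole gene can include exons outside the deleted part.

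Of the 7 genes in the list of FoxF and neighbouring Fox genes, 4 lay below both controls in both KO libraries, and none passed the test over all genes or adjusted over the list alone. If all 4 libraries were interchangeable, chance would place both KO libraries beyond both controls, in either direction, for 33.3% of genes. Over all 14812 genes tested, 2739 lay below both controls in both KO libraries. Besides Foxf2, the 4 genes of the list were Foxq1, Foxc1 and Foxl1. Foxq1, at 31558170 to 31560974 on the same chromosome as Foxf2, had 11.6 and 19.3 CPM in controls and 2.81 and 7.8 CPM in KO. Foxc1, at 31806646 to 31810635 there, had 1.11 and 0.479 CPM in controls and 0.0759 and 0.147 CPM in KO, near the floor of 3 counts (0.107 to 0.132 CPM). Foxl1, a mesenchymal gene on another chromosome beside Foxf1, had 10.2 and 9.65 CPM in controls and 2.96 and 5.55 CPM in KO. Foxf1, the closest paralog of Foxf2, overlapped between groups, at 237.4 and 320.3 CPM in controls and 87 and 329.3 CPM in KO. Its log2 fold change was −0.42 (SE 0.70), −1.68 within batch 1 (adjusted p = 0.00132), 0.24 without KO replicate 1 (adjusted p = 0.79) and 0.18 under scaling to stromal genes. Fendrr, the noncoding gene beside Foxf1, had 33.9 and 36 CPM in controls and 8.5 and 35.1 CPM in KO. The list had median log2 differences from the control mean of −1.66 in KO replicate 1 and −0.78 in KO replicate 2. All stromal genes had a median of −1.73 in KO replicate 1. The list includes Foxf2, the deleted gene, and was not tested without it. As a group the list was lower by limma's camera (adjusted p = 0.000131, or 0.0697 without KO replicate 1, and adjusted p = 0.6 with an estimated correlation).

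**Figure D1:**
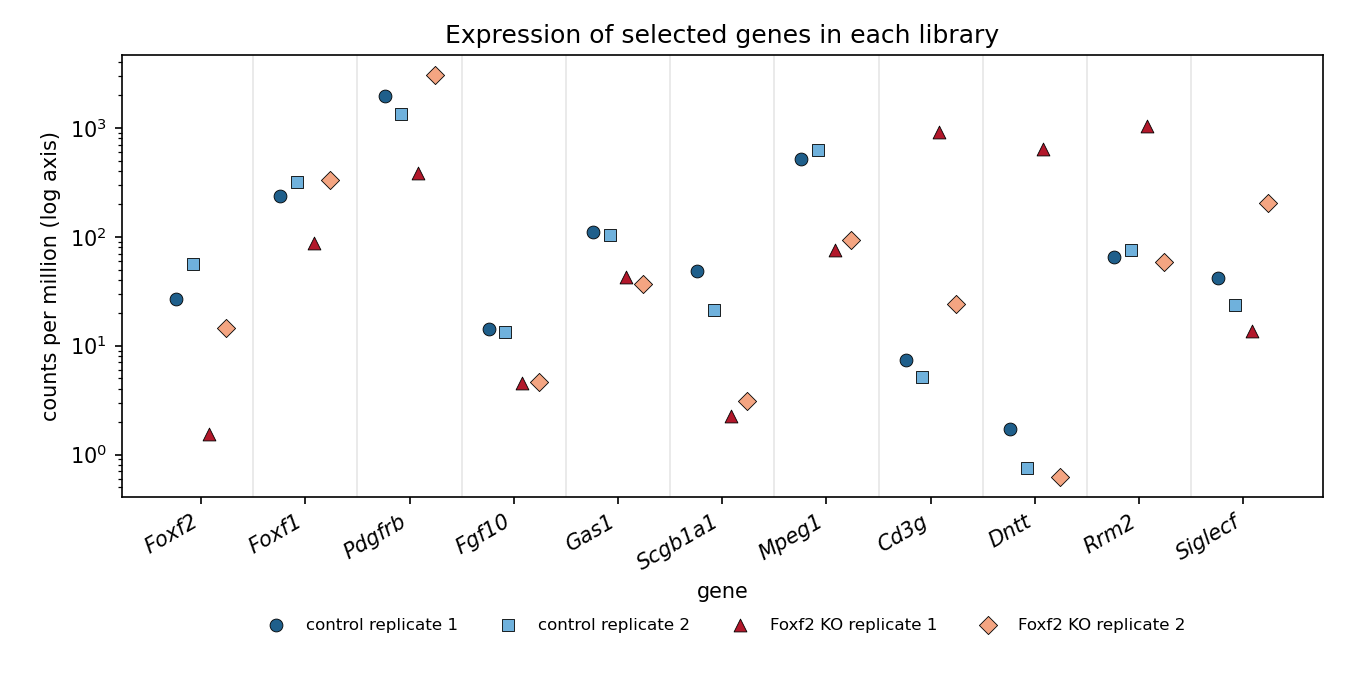
CPM on a log axis for 11 genes, with 1 point per library: circles and squares are control replicates 1 and 2, triangles and diamonds are Foxf2 KO replicates 1 and 2. Foxf2, Fgf10, Gas1, Scgb1a1 and Mpeg1 lay below both controls in both KO libraries, Cd3g lay above, Dntt and Rrm2 were high in KO replicate 1 alone (637.7 and 1033 CPM), and Siglecf was highest in KO replicate 2 (203.7 CPM).

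The second comparison asked which genes differed between Foxf2 KO and control cells. Among genes at a mean of at least 5 CPM, those with the smallest p on the lower side were Mpeg1, Scgb1a1, Padi2, Trappc8 and Cstdc6. On the higher side they were Prkcq, Unc5cl, Sytl1, Fhl3 and St8sia1. None of the 10 passed (adjusted p = 0.755 for each). Mpeg1, which encodes the pore-forming protein perforin-2 of phagocytes, averaged 568.5 ± 72.4 CPM in controls and 83.8 ± 12.7 CPM in KO (SD, n = 2 each), a log2 fold change of −2.76 (SE 0.41). Scgb1a1, the secretoglobin of club cells, averaged 35.1 ± 19.4 CPM in controls and 2.68 ± 0.575 CPM in KO, a log2 fold change of −3.71 (SE 0.62). Padi2, a protein deiminase, stood at 76.6 and 119.3 CPM in controls and 22.9 and 15.3 CPM in KO. Trappc8, a subunit of a vesicle tethering complex, stood at 60.5 and 62.8 CPM in controls and 22 and 19.7 CPM in KO. Cstdc6, of the stefin A cluster, had a log2 fold change of −2.20, and its near-identical neighbours make its counts uncertain.

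Prkcq, the protein kinase C theta of T cells and other leukocytes, averaged 22.2 ± 1.43 CPM in controls and 98 ± 21.2 CPM in KO, a log2 fold change of 2.14 (SE 0.37). Unc5cl had 2.31 and 1.79 CPM in controls and 27.5 and 13.7 CPM in KO. Sytl1, a synaptotagmin-like vesicle protein, had 19.3 and 12.3 CPM in controls and 59 and 119.3 CPM in KO. Fhl3, a LIM-domain protein, had 0.8 and 1.08 CPM in controls and 5.2 and 19.9 CPM in KO. St8sia1, the sialyltransferase that makes the ganglioside GD3, had 0.711 and 0.798 CPM in controls and 23.4 and 4.38 CPM in KO. DESeq2 called all of these 10 genes except Trappc8 (adjusted p = 0.22).

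Over all 14812 genes tested, edgeR's quasi-likelihood test called 0 genes at an adjusted p of 0.05 or less, and the smallest adjusted p was 0.755. At an unadjusted p under 0.05 there were 318 genes, 152 higher and 166 lower in KO. DESeq2 called 111 genes (99 higher, 12 lower) and limma-voom called 0. Both KO libraries lay above both controls for 2759 genes and below both for 2739, together 37.1% of genes. Chance would give 33.3% if all 4 libraries were interchangeable. KO replicate 1 stood apart from the others, so the difference from 33.3% cannot be read as an effect shared by the KO libraries. The within-batch fit, which sets KO replicate 1 against both controls with 1 residual degree of freedom, called 8629 genes (4500 higher, 4129 lower), and leaving out KO replicate 2 gave 8712. Leaving out KO replicate 1 gave 63 genes (53 higher, 10 lower), leaving out control replicate 1 gave 33 and control replicate 2 gave 21.

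The changes of the KO libraries were also compared with each other across the 14812 genes. The log2 differences from the control mean correlated between KO replicates 1 and 2 at r = 0.0838 (covariance 0.0497). A simulated unchanged library in place of KO replicate 2, set against the same controls, gave r = 0.092 on average over 20 simulated sets (0.075 to 0.107), and a covariance of 0.0421 (0.034 to 0.0491). Among the 7406 genes with the larger change in KO replicate 1, KO replicate 2 lay beyond both controls in the same direction for 39%, against 37.4% for the unchanged library (36.1% to 38.4%). The unchanged library was given the spread of the controls. KO replicate 2 differed more from the controls (chi-square per gene 84.1 and 76.3) than they did from each other (46.6). A wider spread alone could raise its share and covariance, so these values cannot show an effect shared by the KO libraries. These comparisons are across genes, which are not independent replicates.

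Without KO replicate 1, the 63 calls compare KO replicate 2 alone with both controls, and the lone library is assumed to vary like the controls. Siglecf, a surface lectin of eosinophils, had 203.7 CPM in KO replicate 2, 41.6 and 23.4 CPM in the controls and 13.5 CPM in KO replicate 1 (log2 fold change 2.65, adjusted p = 0.0406). Ccr3, the eotaxin receptor, had 362.2 CPM there against 68 and 37.5 CPM in the controls and 17.7 CPM in KO replicate 1. The higher calls thus went both ways in KO replicate 1: Siglecf and Ccr3 lay below both controls there, and Prkcq and Sytl1 above both. Of the 10 lower calls, 7 lay below both controls in KO replicate 1 too, among them Mpeg1, Padi2, Trappc8, Cstdc6 and Gas1, and 3 lay above both there (Hmgn2, Art4 and 2610035D17Rik). Of the 63 calls, 49 are also past the threshold in the authors' deposited table, 21 of them in the same direction. Gas1, a hedgehog co-receptor, had 111.5 and 104.3 CPM in controls and 42.6 and 36.9 CPM in KO (log2 fold change −1.55 without KO replicate 1, adjusted p = 0.0351). Siglecf, Ccr3, Hmgn2, Art4 and 2610035D17Rik were chosen after their values were seen.

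The third comparison tested gene lists fixed before the data were examined. Of 30 lists, 20 passed camera with a preset correlation of 0.01, 18 lower and 2 higher in KO, and no member of any list passed over all genes. Adjusted over the list alone, 1 gene passed, Scgb1a1 in the epithelial list. With a correlation estimated from the data 0 lists passed (smallest adjusted p = 0.6 with an estimated correlation), and fry called 0 (smallest adjusted p = 0.437). In simulated counts camera with an estimated correlation missed a list shifted by 2 on the log2 scale. Its failures here and below therefore cannot show that a list is unchanged. Without KO replicate 1, 10 lists passed with the preset correlation and 0 with an estimated one (smallest adjusted p = 0.84 with an estimated correlation). Of the 20 lists, 8 passed in that fit in the same direction and 1, cell cycle, in the opposite direction. Both fits hold the same other libraries. Within batch 1, 20 lists passed with the preset correlation and 0 with an estimated one (smallest adjusted p = 0.647 with an estimated correlation).

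Lung fibroblast genes lay lower in both KO libraries. The alveolar fibroblast list, markers of the lipid-bearing fibroblasts beside alveoli, had 11 of 13 genes below both controls, with median log2 differences from the control mean of −1.52 in KO replicate 1 and −0.69 in KO replicate 2. Fgf10, a growth factor for the epithelium, had 14.1 and 13.2 CPM in controls and 4.51 and 4.63 CPM in KO. Limch1 had 65.8 and 100.7 CPM in controls and 20.6 and 31.6 CPM in KO, and the methyltransferase Inmt had 19.6 and 19.4 CPM in controls and 5.42 and 8.31 CPM in KO. The list passed (adjusted p = 7.06e-08, or 6.84e-05 without KO replicate 1, and adjusted p = 0.6 with an estimated correlation). The adventitial fibroblast list had 9 of 13 genes below both controls, with medians of −1.08 and −0.62 (adjusted p = 2.66e-05, or 0.0131 without KO replicate 1, and adjusted p = 0.6 with an estimated correlation). Its median difference between control replicate 2 and control replicate 1 was −0.76. In that list Scara5 had 149.7 and 46.3 CPM in controls and 46 and 35.3 CPM in KO, and Ly6a had 147 and 68.2 CPM in controls and 46.9 and 51.3 CPM in KO. Under scaling to stromal genes their log2 fold changes were 0.023 and 0.0071. Both are among the stromal genes whose average that scaling holds equal across libraries, so this is no independent check. Beside these medians, all stromal genes had a median of −1.73 in KO replicate 1, which also carried Dntt at 637.7 CPM.

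Contractile lists followed the same order with smaller differences in KO replicate 2. Smooth muscle markers had 10 of 16 genes below both controls and medians of −1.84 in KO replicate 1 and −0.28 in KO replicate 2. Myocd, the cofactor that drives smooth muscle genes, had 3.51 and 5.22 CPM in controls and 0.683 and 2.06 CPM in KO. The list passed (adjusted p = 3.8e-06, or 0.0403 without KO replicate 1, and adjusted p = 0.6 with an estimated correlation). Alveolar myofibroblast markers had 5 of 10 genes below both controls and medians of −2.05 and −0.33 (adjusted p = 0.000149, or 0.134 without KO replicate 1, and adjusted p = 0.6 with an estimated correlation). Pdgfra, the receptor that marks these cells, had 365 and 289.4 CPM in controls and 76.1 and 227.2 CPM in KO, and Stc1 had 55.3 and 77.5 CPM in controls and 24.3 and 45.6 CPM in KO.

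Pericyte markers moved apart between the KO libraries. Of 20 genes, 19 lay below the control mean in KO replicate 1 (median −1.48) and 16 above it in KO replicate 2 (median 0.82), and 0 lay beyond both controls in the same direction in both. Pdgfrb, the gene of the sorted receptor, had 1942 and 1328 CPM in controls and 387.8 and 3040 CPM in KO. Emid1 had 113.9 and 98.7 CPM in controls and 107.4 and 209.4 CPM in KO, and the potassium channel gene Kcnj8 had 51 and 36.1 CPM in controls and 18.4 and 37.3 CPM in KO. The list did not pass (adjusted p = 0.107), and camera placed it lower while its median log2 fold change was 0.03. Within batch 1 it was lower (adjusted p = 0.000289, with adjusted p = 0.688 with an estimated correlation). Without KO replicate 1 it was higher (adjusted p = 6.36e-05, with adjusted p = 0.84 with an estimated correlation).

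**Figure D2:**
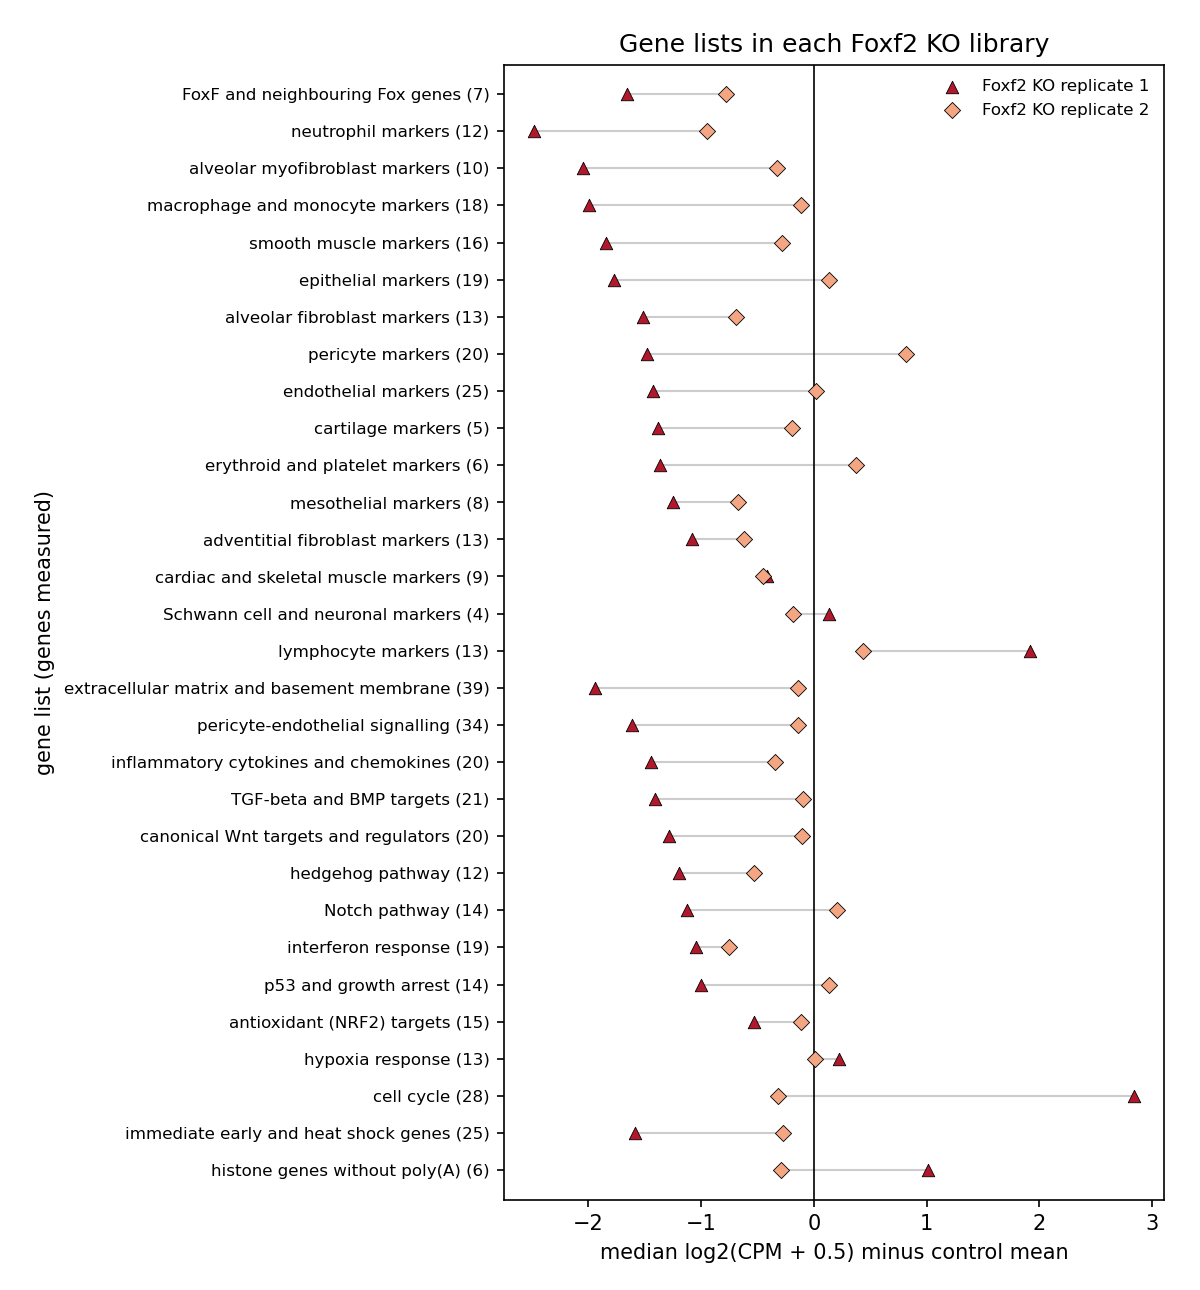
Median log2(CPM + 0.5) difference from the control mean for the 30 lists with at least 3 measured genes, in Foxf2 KO replicate 1 (triangles) and replicate 2 (diamonds), with the number of genes measured after each name. Most lists lay to the left in KO replicate 1, such as neutrophil markers at −2.48, with cell cycle at 2.84 and lymphocyte markers at 1.92 to the right, and pericyte markers lay on opposite sides of 0.

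Endothelial and epithelial lists were lower in KO replicate 1 and near the controls in KO replicate 2. Endothelial markers had medians of −1.42 and 0.02, with 2 of 25 genes below both controls. Cav1, the caveolin of capillaries, had 348.8 and 417 CPM in controls and 139.1 and 251.3 CPM in KO, and Ramp2, a subunit of the adrenomedullin receptor, had 65.5 and 102 CPM in controls and 29.2 and 70.7 CPM in KO. The list passed (adjusted p = 0.000231), with adjusted p = 0.683 with an estimated correlation, and without KO replicate 1 the adjusted p was 0.777. Epithelial markers had medians of −1.77 and 0.13, with 6 of 19 genes below both controls (adjusted p = 0.000563, or 0.777 without KO replicate 1, and adjusted p = 0.6 with an estimated correlation). Ager, of flat alveolar type 1 cells, had 39.5 and 64.1 CPM in controls and 11.8 and 38.8 CPM in KO, and the water channel gene Aqp5 had 6.22 and 8.1 CPM in controls and 1.4 and 4.19 CPM in KO. Other members differed: the adhesion gene Epcam had 1.91 and 2.95 CPM in controls and 42.9 and 1.03 CPM in KO, and the keratin gene Krt18, the 1 gene above both controls in both KO libraries, had 3.47 and 3.95 CPM in controls and 5.62 and 6.4 CPM in KO. Mesothelial markers had medians of −1.25 and −0.67, with 4 of 8 genes below both controls (adjusted p = 0.00031, or 0.0144 without KO replicate 1 and 0.0645 within batch 1, and adjusted p = 0.6 with an estimated correlation). Rspo1, a secreted Wnt enhancer, had 13.7 and 8.97 CPM in controls and 2.77 and 2.13 CPM in KO.

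Neutrophil and macrophage lists had medians below 0 and the lymphocyte list above 0 in both KO libraries, with single members going other ways. Neutrophil markers had 10 of 12 genes below both controls and medians of −2.48 in KO replicate 1 and −0.95 in KO replicate 2 (adjusted p = 3.51e-07, or 1.27e-05 without KO replicate 1, and adjusted p = 0.6 with an estimated correlation). S100a8, a calcium-binding protein of neutrophils, had 3359 and 2604 CPM in controls and 506.1 and 1083 CPM in KO, and the chemokine receptor gene Cxcr2 had 213.7 and 170.9 CPM in controls and 48.3 and 102.9 CPM in KO. Retnlg, a resistin-like gene in that list, had 1321 and 904.2 CPM in controls and 222.6 and 2716 CPM in KO. Macrophage and monocyte markers had 8 of 18 genes below both controls, with 7 above the control mean in KO replicate 2, and medians of −2.0 and −0.11 (adjusted p = 1.76e-05, or 0.496 without KO replicate 1, and adjusted p = 0.6 with an estimated correlation). Marco, a scavenger receptor, had 13.2 and 6.54 CPM in controls and 0.303 and 1.36 CPM in KO, and the complement gene C1qb had 49.7 and 34.3 CPM in controls and 11.2 and 22.2 CPM in KO, while Adgre1, the F4/80 antigen, had 261.7 and 245.2 CPM in controls and 58.9 and 607.8 CPM in KO. Lymphocyte markers had 7 of 13 genes above both controls and medians of 1.92 and 0.43 (adjusted p = 4.78e-05, or 0.0238 without KO replicate 1, and adjusted p = 0.6 with an estimated correlation). The CD3 chain gene Cd3g had 7.38 and 5.1 CPM in controls and 922.7 and 24.1 CPM in KO, and Cd3d had 10.2 and 10.1 CPM in controls and 471.7 and 37.1 CPM in KO. Cd4 had 2.44 and 2.23 CPM in controls and 400.8 and 1.43 CPM in KO, and Cd8a, given below, also lay under both controls in KO replicate 2.

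Of the other cell type lists, none passed. Erythroid and platelet markers had medians of −1.37 in KO replicate 1 and 0.37 in KO replicate 2 (adjusted p = 0.246), cartilage markers −1.39 and −0.19 (adjusted p = 0.535), cardiac and skeletal muscle markers −0.41 and −0.45 (adjusted p = 0.144), and Schwann cell and neuronal markers 0.13 and −0.19 (adjusted p = 0.952). For the last list camera's direction was lower while the median log2 fold change was 0.11.

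Genes of pericyte-endothelial signalling and of the matrix were lower as groups, most of it in KO replicate 1, where all stromal genes had a median of −1.73 and thymocyte genes summed to 8885 CPM. The signalling list had 16 of 34 genes below both controls and medians of −1.61 and −0.14 (adjusted p = 7.06e-08, or 0.356 without KO replicate 1, and adjusted p = 0.6 with an estimated correlation). Its members with the smallest p were Slit3, Sema3a and Slit2, and others such as Sema3c (159.1 and 151.2 CPM in controls, 47.1 and 158.9 CPM in KO) overlapped. Slit3 had 49.7 and 37.9 CPM in controls and 7.63 and 17.9 CPM in KO, and Slit2 had 46.6 and 36.1 CPM in controls and 8.35 and 19.9 CPM in KO. Sema3a had 9.87 and 6.82 CPM in controls and 2.05 and 3.02 CPM in KO. Extracellular matrix and basement membrane genes had 9 of 39 below both controls and medians of −1.94 and −0.14 (adjusted p = 7.06e-08, or 0.68 without KO replicate 1, and adjusted p = 0.6 with an estimated correlation), with −0.63 between the controls. Col13a1, a transmembrane collagen, had 14.5 and 24.1 CPM in controls and 5.05 and 7.54 CPM in KO, and the cross-linking enzyme gene Loxl2 had 33.3 and 29 CPM in controls and 12.1 and 16.7 CPM in KO.

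Hedgehog, TGF-beta and BMP, and Wnt lists were also lower as groups, by less than the stromal median of −1.73 in KO replicate 1. The hedgehog list had 8 of 12 genes below both controls and medians of −1.20 and −0.53 (adjusted p = 0.000134, or 0.00295 without KO replicate 1, and adjusted p = 0.6 with an estimated correlation). Besides Gas1, the co-receptor gene Boc had 150.6 and 95.1 CPM in controls and 30.7 and 80.7 CPM in KO, and Hhip, a hedgehog-binding inhibitor, had 107.4 and 86.7 CPM in controls and 22.9 and 63.1 CPM in KO. TGF-beta and BMP targets had 11 of 21 genes below both controls and medians of −1.41 and −0.10 (adjusted p = 3.8e-06, or 0.22 without KO replicate 1, and adjusted p = 0.6 with an estimated correlation). Ccn1 had 430.5 and 566.8 CPM in controls and 168.5 and 367.1 CPM in KO, and Id4 had 3.38 and 6.54 CPM in controls and 1.48 and 1.91 CPM in KO. The Wnt list had medians of −1.28 and −0.10, with 5 of 20 genes below and 2 above both controls (adjusted p = 0.0182, or 0.684 without KO replicate 1 and 0.0581 within batch 1, and adjusted p = 0.6 with an estimated correlation). Its members went both ways: Tcf7 and Lef1, which are also transcription factors of developing T cells, had 1333 and 433.6 CPM in KO replicate 1, against 22.2 and 22.5 CPM in control replicate 2 and 17.2 and 26.2 CPM in KO replicate 2. The secreted Wnt inhibitor gene Notum had 14.4 and 14.1 CPM in controls and 4.63 and 7.46 CPM in KO. The Notch list did not pass (medians −1.13 and 0.20, adjusted p = 0.199, or 0.0289 and lower within batch 1, with adjusted p = 0.647 with an estimated correlation).

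Cell cycle genes went opposite ways in the KO libraries. Of 28 genes, 27 lay above the control mean in KO replicate 1 (median 2.84) and 26 below it in KO replicate 2 (median −0.32). In KO replicate 1 all 14 genes of a thymocyte list, chosen after the data were seen, also lay above both controls (median 7.46, summing to 8885 CPM). Rrm2, a subunit of ribonucleotide reductase, had 64.9 and 74.8 CPM in controls and 1033 and 58.4 CPM in KO. Birc5 had 21.6 and 22.3 CPM in controls and 241.3 and 17.9 CPM in KO, and the mitotic kinase gene Aurka had 20.1 and 18.1 CPM in controls and 180.1 and 20.7 CPM in KO. The list was higher in the comparison of all libraries (adjusted p = 1.33e-05, with adjusted p = 0.637 with an estimated correlation). Without KO replicate 1 it was lower (adjusted p = 6.36e-05, with adjusted p = 0.84 with an estimated correlation).

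Interferon and inflammatory genes lay lower as groups, beside neutrophil markers with medians of −2.48 and −0.95 and stromal genes with a median of −1.73 in KO replicate 1. The interferon list had 14 of 19 genes below both controls and medians of −1.04 and −0.76 (adjusted p = 1.68e-06, or 6.84e-05 without KO replicate 1, and adjusted p = 0.6 with an estimated correlation). The antiviral genes Rsad2 and Oasl2 had 47.6 and 177.2 CPM in control replicate 1, 26 and 91.8 CPM in control replicate 2, 8.69 and 27.9 CPM in KO replicate 1, and 15.4 and 58.1 CPM in KO replicate 2. The median difference of this list between control replicate 2 and control replicate 1 was −0.67. Inflammatory cytokines and chemokines had 12 of 20 genes below both controls and medians of −1.44 and −0.35 (adjusted p = 2.68e-05, or 0.134 without KO replicate 1, and adjusted p = 0.6 with an estimated correlation), and their median difference between control replicate 2 and control replicate 1 was −0.53. Il1b had 631.2 and 565.2 CPM in controls and 151.4 and 221.1 CPM in KO, the neutrophil chemokine gene Cxcl1 had 11.3 and 7.1 CPM in controls and 2.96 and 2.94 CPM in KO, and the adhesion molecule gene Vcam1 had 189.3 and 129 CPM in controls and 64.8 and 74.7 CPM in KO.

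Of the remaining lists, only immediate early and heat shock genes passed. Antioxidant targets of NRF2 had medians of −0.53 and −0.11 (adjusted p = 0.383). Within that list the cystine transporter gene Slc7a11 had 21.4 and 18.1 CPM in controls and 29.7 and 58.8 CPM in KO, and the heme oxygenase gene Hmox1 had 159.5 and 149.6 CPM in controls and 25.1 and 89.9 CPM in KO. The p53 and growth arrest list had medians of −1.0 and 0.14 (adjusted p = 0.337) and the hypoxia list 0.22 and 0.01 (adjusted p = 0.96). Immediate early and heat shock genes, which rise during tissue digestion, had 11 of 25 genes below both controls and medians of −1.59 and −0.27 (adjusted p = 0.000287, or 0.353 without KO replicate 1, and adjusted p = 0.6 with an estimated correlation). Socs3 had 241.5 and 238.1 CPM in controls and 64.9 and 163.9 CPM in KO, and Klf4 had 32.4 and 32.9 CPM in controls and 8.65 and 21.8 CPM in KO. Histone genes without poly(A) tails had medians of 1.01 and −0.29 (adjusted p = 0.845).

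The authors' deposited table gives their own DESeq2 comparison of the study. Its smallest p-values belong to Cd8a, Cd3g, Cd8b1, Lck and Dntt, genes of T-cell receptor complexes, signalling and rearrangement, with log2 fold changes of 7.96, 7.21, 7.78, 7.37 and 8.47 in the authors' deposited table. Cd8a had 784.5 CPM in KO replicate 1, 1.51 CPM in KO replicate 2 and 3.16 and 2.91 CPM in the controls in the deposited counts. In the authors' deposited table Foxf2 has a log2 fold change of −4.79 (SE 0.46, adjusted p = 6.09e-24) and Pdgfrb one of −2.08 (SE 0.26, adjusted p = 9.87e-15). The authors' deposited table lists 14901 genes, of which 7712 are past an adjusted p of 0.05, 3818 higher and 3894 lower. Across genes, which are not independent replicates, its log2 fold changes correlated at r = 0.956 with KO replicate 1 minus the control mean and at 0.0725 with KO replicate 2 minus the control mean. Of the authors' calls tested here, KO replicate 1 lay beyond both controls in the same direction for 99.96%, and KO replicate 2 for 38.6%. Chance alone gives 33.3% if KO replicate 2 varies like the controls, before any effect of the shared controls. DESeq2 with the batch term, added after the data were seen, called 7301 genes on the deposited counts, and 6946 of these are also past the threshold in the authors' deposited table.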

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

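Scaling to stromal genes, DESeq2 with the batch term, and list tests without KO replicate 1 with an estimated correlation were chosen after the data were seen. The count of 0 changed genes held under DESeq2 size factors, upper-quartile scaling, both filters, limma-voom, fewer gene models, a threshold of 0.1 and stromal scaling, and a minimum fold change could only keep it at 0. It was 3 with a replicate block, 111 with DESeq2, 8629 with the batch term, 7301 with DESeq2 and the batch term, and 21 to 8712 without 1 library. The batch term and the fit without KO replicate 2 both leave KO replicate 1 against the controls. No pairing by replicate number was seen: deviations of same-numbered libraries from their group means correlated at −0.0175. KO replicate 1 stood apart from all other libraries, so this value cannot exclude a pairing. The 20 lists became 0 with an estimated correlation, 0 with fry, 0 without KO replicate 1 with an estimated correlation, and 10 to 22 without 1 library; the cause was not tested. Foxf2 kept its direction in all alternatives. Its log2 fold change passed at −4.74 with the batch term and at −4.77 with DESeq2 and the batch term, and ran from −4.80 (without KO replicate 2, which also passed) to −1.52 without 1 library.
Over the named genes, 733 of the alternative values kept direction and side of the threshold, 208 kept direction and passed, and 13 changed sign. No named gene passed in the main edgeR comparison. Camera compares a list with all other genes, so its calls cannot test a change of scaling. Over the lists, 329 kept both, 76 lost the call, 11 gained it, and 31 turned direction. Under stromal scaling the log2 fold change turned to 0.175 for Foxf1, 0.229 for Kcnj8, 0.0231 for Scara5 and 0.00712 for Ly6a. Of these, Kcnj8, Scara5 and Ly6a are among the genes that set that scale. With DESeq2 and the batch term it was −0.00702 for Emid1. Leaving out 1 library gave ranges across 0 of −1.74 to 0.24 for Foxf1, −2.1 to 0.00713 for Fendrr, −0.0423 to 0.979 for Emid1, −0.702 to 7.36 for Cd4, −1.24 to 4.08 for Epcam, −0.237 to 5.98 for Tcf7, −0.258 to 3.83 for Rrm2 and −0.288 to 3.4 for Birc5. The end across 0 was the fit without KO replicate 1, or without KO replicate 2 for Emid1. Leaving out either control turned none of these signs. The KO libraries differed in such genes: Cd4 had 400.8 CPM in KO replicate 1 and 1.43 CPM in KO replicate 2. List medians, for lists whose test direction turned, ranged without 1 library from −1.72 to 0.754 for pericyte markers, −1.58 to −0.0265 for endothelial, −1.69 to 0.388 for erythroid and platelet, −0.197 to 0.251 for Schwann cell and neuronal, −0.754 to 0.156 for cardiac and skeletal muscle and −1.21 to 0.0263 for cartilage markers. They ranged from −1.36 to 0.195 for Notch, −0.323 to 2.79 for cell cycle, −1.16 to 0.128 for p53, −0.00397 to 0.389 for hypoxia and −0.345 to 3.2 for histone genes. With an estimated correlation the lists that turned without KO replicate 1 had the same medians there: 0.754 for pericyte, −0.0265 for endothelial, 0.388 for erythroid, −0.365 for cartilage, 0.195 for Notch, −0.323 for cell cycle, 0.128 for p53, −0.00397 for hypoxia and −0.345 for histone genes. Lists that did not pass in the comparison of all libraries also turned in test direction: Schwann cell markers with no filter (median 0.652), a replicate block (−0.0176), the batch term (0.308) and stromal scaling (1.30), hypoxia genes with the strict filter (0.0236), limma-voom (0.123) and fry (0.107), and histone genes with fry (0.551). The cause of these was not tested. Depth was not varied. At these depths and the simulated spread of all 4 libraries, the edgeR test recovered 98% of genes changed by 4 on the log2 scale and 0% of those changed by 1, against 62% of the latter at the spread of the controls. The simulation held no outlying library, so these shares can overstate what the test finds here. Cd4 was fitted at 6.42 in the comparison of all libraries and did not pass.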

Other observations

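The gene groups, genes and tests of this part were all chosen after the values were seen, except the fixed lists.

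Interferon-induced genes did not move as one in KO replicate 2. Most of the interferon list lay lower there, as described above, while Ifi44l reached 27.1 CPM against 0.133 and 0.16 CPM in the controls and 0 counts in KO replicate 1. Its neighbour Ifi44 reached 52.3 CPM there, against 3.91 and 1.48 CPM in the controls and 1.33 CPM in KO replicate 1. Both passed edgeR's quasi-likelihood test without KO replicate 1 (adjusted p = 0.00435 and 0.0376), which rests on that library alone. Stfa1, a cysteine protease inhibitor of the stefin A cluster with near-identical copies, had 254.6 CPM in KO replicate 2, against 12 CPM in each control and 2.16 CPM in KO replicate 1. Retnla, a secreted resistin-like protein of macrophages and epithelium in type 2 responses, had 124.2 CPM there, against 17.4 and 14.6 CPM in the controls and 19.8 CPM in KO replicate 1. Mgp, the matrix Gla protein that inhibits calcification and binds BMPs, lay lower in both KO libraries, at 149.2 and 107.8 CPM against 403.5 and 323.6 CPM in the controls (log2 fold change −1.75 without KO replicate 1, adjusted p = 0.0446). The chromatin protein gene Hmgn2 went opposite ways, at 935.1 CPM in KO replicate 1 and 129.9 CPM in KO replicate 2, against 353 and 359.6 CPM in the controls.

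In KO replicate 1, all 14 genes of a thymocyte list (4 of them also in the lymphocyte list) lay above both controls and summed to 8885 CPM, led by Lck at 2811 CPM, and 3 of them lay above both controls in KO replicate 2. An effect of Foxf2 deletion shared by the KO libraries is argued against by the median log2 difference of these genes in KO replicate 2, −0.386. Mature T cells from blood or lung are argued against by Rag1, Rag2, Dntt and Ptcra at a median of 7.95, and a thymus library under a lung label by surfactant genes at 26.6% of the control mean. Thymus cells in the preparation are a candidate source, with the thymocyte genes at a median of 7.46 and the 11 larger non-lymphoid cell type lists between −2.48 and −0.41, although thymocytes should not carry CD140b and a clean capture would remove them. Of 5 thymic epithelial genes, Ccl25 had 6.79 CPM in KO replicate 1 against 2.18 and 2.91 CPM in the controls. Psmb11 had 29 counts there against 0 in each control. Prss16 had 82 counts against 56 and 39, Aire had 18 against 0 and 1, and Foxn1 had 1 against 0. An effect on the thymus of the mouse or mice behind that library stays untested.

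Foxf2 lay lower in both KO libraries without passing the test. Dilution of lung RNA in KO replicate 1 is argued against as the whole cause, since 0% of the stromal genes had a log2 change there at or below that of Foxf2, which lay −2.53 from their median. A lower share of pericytes in KO replicate 2 is argued against by the pericyte markers, at a median of 0.819 above the control mean. A lower share of fibroblasts there stays open. The alveolar and adventitial fibroblast lists had medians of −0.69 and −0.62 in that library, where Foxf2 lay at −1.395. The comparison with all stromal genes covered KO replicate 1 only. Deletion of Foxf2 in Pdgfrb-expressing cells predicts a lower ratio of Foxf2 to Pdgfrb in both KO libraries. The highest KO ratio lay −1.54 from the lowest control ratio on the log2 scale. This cannot decide the question, since Pdgfrb itself was higher in KO replicate 2, at 3040 CPM against 1942 and 1328 CPM in controls. The ratio also differed between the controls, at 1.39% and 4.23%. The lone batch 2 library is a KO library, so for KO replicate 2 the batch stays open.

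In KO replicate 2, all 10 genes of an eosinophil list lay above both controls, led by Alox15 at 1664 CPM and Prg2 at 1394 CPM, against 395 and 178.8 CPM and 392.2 and 186.4 CPM in the controls. Counts of the Ear genes in that list are uncertain, as they are near-identical copies. More eosinophils in that library may be the source, with a median log2 difference of 2.46, although a clean CD140b capture would remove them. In KO replicate 1 the median of these genes was −1.26, the opposite direction to KO replicate 2. Relative to the stromal genes, which also lay low in KO replicate 1, it was 0.472. Its standard error of 0.257 is across genes of 1 library, which are not independent replicates. On these values an effect of Foxf2 deletion shared by the KO libraries stays open. Sequencing or library batch cannot be told apart from it either, since 0 control libraries are in batch 2.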
